A study of Homo sapiens with 4 samples.

How the data were processed

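RNA from UV-crosslinked PC-3 cells was immunoprecipitated for MTA1 and purified, with an optional fragmentation step, per the labels' protocols. Files were read for the 2 immunoprecipitate libraries, and each also carried columns for the input of the same number. Columns were given to libraries by their names. The submitters' processing notes name DESeq2, with no role or version. The aligner, peak caller, genome build, strand setting and any depletion of rRNA were not given in the sources used here.

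Per the file headers, each line was a peak called in 1 library, with its position, strand, gene, position class and gene type. The authors deposited whole-number counts for the immunoprecipitate and the input in columns whose names say normalized, and RPKM values in columns without that word; the values show that these names are exchanged. All RPKM values followed from the counts, the peak length and 1 total per library, within rounding. The authors' deposited log2 value of each peak equalled the log2 ratio of both RPKM values after adding 1 (largest difference 3.73e-14). The lowest was 1.00 in each list. The authors' deposited p-value had 1 value for each pair of counts and stayed under 0.01. With 0 input counts it implied an immunoprecipitate share of the totals of 46.7% and 38.0% in replicates 1 and 2, against 43.2% and 35.9% from the RPKM totals. Peak height and summed depth were a coverage signal, per the file headers, and ranks of peaks used only the authors' log2 value.

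Library totals were recovered from RPKM as the median over peaks with at least 5 counts (about 1916282, 2514776, 1348208 and 2405978 for immunoprecipitate 1, input 1, immunoprecipitate 2 and input 2). Folds over input are ratios of counts scaled by these totals. No pseudocount was added; in medians, an input of 0 was set to 3 counts unless such peaks were left out, and odds ratios had 0.5 added to each cell. Values over both libraries pool the counts of 2 libraries and have an exact 95% interval from the binomial distribution, covering counting error only, as reads without molecular identifiers are not independent molecules. With 0 input counts in both libraries, the fold is a lower bound against 3 counts over both inputs. The median peak had 22 and 20 immunoprecipitate counts and 4 and 6 input counts in replicates 1 and 2, so most single folds are imprecise.

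Coordinates are those of the files, which are 1-based. Gene names, lengths and the positions of small RNAs and rRNA parts came from RefSeq for assembly GRCh38.p14. Of 726 symbols, 689 matched it, with older names matched through synonyms. Of 1226 peaks with a matched symbol, 98.4% lay in that gene's RefSeq span, and this is the basis for using the spans. No genome or exon annotation was used. For this reason, the planned comparison of untranslated and coding regions with uniform placement and the planned test of 5-base words were not run, and the exon and intron classes are the authors'.

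Peak lists were compared by overlap of at least 1 base on the same strand. Each peak of the shorter list was placed uniformly in its gene's RefSeq span, or, for peaks with no matched gene, between the first and last peak with its label. The exact Poisson-binomial distribution gave the p. Genes counted as having a peak only through exonic or intronic peaks on the gene's strand. The background was 20050 protein-coding genes in 10 bins of gene length. Gene lists were tested by the exact stratified hypergeometric test, with Fisher's exact test against all annotated genes for non-coding and mitochondrial lists, and Benjamini-Hochberg adjustment over 27 lists at a threshold of 0.05. A small RNA was called covered when a peak that was not antisense overlapped at least 50% of it, whatever the strand of the small RNA. Concordance was Spearman's and Pearson's correlation of the authors' log2 value over one-to-one best matches, with 100000 random pairings.

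Counts of matched peaks were tested with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest), immunoprecipitate against input, with the log of library total and peak length as offset and no other normalization, since scaling over peaks chosen for their excess would remove it. The biological coefficient of variation was 18.5%. This test was added after the counts were found in the files. Replicates differed by more than sampling noise in both groups (chi-square per degree of freedom of 6.74 for immunoprecipitates and 3.08 for inputs over 247 peaks with at least 10 input counts), and each library was counted as 1 replicate.

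Genes were named by a rule fixed before the data were examined. It takes the 20 protein-coding and 5 non-coding genes with the best mean rank of the authors' log2 value among overlapping peaks, up to 4 members per gene list, MTA1 and all NuRD members, and the 5 genes with the most peaks. Alternatives changed the overlap rule, the share of each list used (the better 50% or 25%), the length bins, the gene assignment, the score and the replicates, and those added later are named in the closing section.

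On simulated data, the test for gene lists gave p under 0.05 in 2.80% of 1000 random lists of 40 among 20050 genes, and in 100% of 300 lists with 4 of 40 members among the genes with a peak in both libraries. The test of shared genes did so in 3.60% of 500 pairs of independent lists. The overlap test did so in 4.45% of 2000 draws of overlaps for 676 peaks, made from invented chances of overlap. These draws placed no peaks in genes, so they check the exact distribution and not the placement. In simulated counts for the comparison of immunoprecipitate with input over 390 matched peaks, edgeR called 16.4% of 67 peaks changed 2-fold, 70.1% of 67 changed 4-fold, 100% of 66 changed 8-fold and 1.05% of 190 unchanged peaks. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.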

Results

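RNA recovered by immunoprecipitation of MTA1 (metastasis-associated 1), a subunit of the nucleosome remodelling and deacetylase (NuRD) complex, was sequenced beside input RNA (RIP-seq). The cells were PC-3, an established human prostate cancer line derived from a bone metastasis that grows without androgen. There were 4 libraries in 2 groups, 2 MTA1 immunoprecipitates and 2 inputs. The series title puts the RNAs that MTA1 contacts, and their link to transcript levels and splicing, at the centre of the study, so the comparisons asked which RNAs exceeded the input and whether both immunoprecipitates gave the same ones. The authors' list for replicate 1 held 852 peaks and that for replicate 2 held 676, with a median length of 291 bases in each. The library totals behind the authors' RPKM values were about 1916282 (immunoprecipitate 1), 2514776 (input 1), 1348208 (immunoprecipitate 2) and 2405978 (input 2). The peaks held 79632 and 53915 immunoprecipitate counts in replicates 1 and 2, against 14128 and 13657 input counts. Each listed peak had at least 10 immunoprecipitate counts and more than 2-fold excess over input, so an RNA missing from the lists may have been present without such an excess. The labels do not say whether the replicates came from separate cultures, so the spread between these samples may be technical. Only the p-values of the count tests on matched peaks measure that spread. The other p-values compare genes, peaks or reads with chance and hold no spread between libraries.

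The strongest excess over input lay in the ribosomal RNA (rRNA) cluster on the short arm of chromosome 21, which encodes the precursor of 18S, 5.8S and 28S rRNA. It held 81 peaks (9.51%) in replicate 1 and 80 (11.8%) in replicate 2. Of the counts in peaks, it held 62.4% and 61.9% in the immunoprecipitates and 39.4% and 44.8% in the inputs. Of the library totals, its peaks held 2.59% and 2.47% in the immunoprecipitates, against 0.221% and 0.254% in the inputs. With counts summed over the peaks of each part on the plus strand, the 5' external transcribed spacer of the precursor was 161-fold (13 peaks, 95% interval 130 to 203) and 129-fold (13 peaks, 103 to 163) above input in replicates 1 and 2. Summed in the same way, the 3' external spacer was 42.3-fold (21.2 to 99.1) and 42.5-fold (19.1 to 118), internal transcribed spacer 2 48.7-fold (44.1 to 54.0) and 25.4-fold (23.4 to 27.5), and internal transcribed spacer 1 18.8-fold (17.1 to 20.6) and 12.2-fold (11.3 to 13.2) above input, against 4.30-fold (3.82 to 4.85) and 3.93-fold (3.45 to 4.48) for mature 28S rRNA. The median fold of single peaks, among those with at least 1 input count, was 134 and 174 in the 5' external spacer, 80.9 and 121 in internal spacer 1, 96.3 and 78.9 in internal spacer 2, 40.7 and 39.5 in the 3' external spacer and 4.28 and 3.83 in 28S rRNA. Sums and medians gave opposite orders of the internal spacers in replicate 2, and of the replicates in the 5' external spacer and internal spacer 1, while 28S rRNA was lowest by both. The 5' external spacer peaks covered 6153 and 5023 bases at 1620 and 1138 counts per kilobase, against 13.2 and 15.7 in input, and the 28S peaks 837 and 547 bases at 1416 and 1351, against 432 and 614. The spacer sequences are removed during rRNA maturation. The cluster was taken as all chromosome 21 peaks that end before a fixed position, so it also holds peaks outside the annotated copies of the precursor. On the plus strand these were 13 in each library and summed to 281-fold (186 to 449) and 238-fold (152 to 395) above input, higher than any annotated part. On the plus strand, the median fold of the 25 spacer peaks was 96.3 in replicate 1 and 85.7 in replicate 2, against 4.28 and 3.83 for the 2 peaks over mature rRNA (exact permutation test over 351 splits, two-sided, p = 0.00285 in each library, the smallest p these numbers of peaks allow). Peaks within a library are not independent replicates, and this comparison was added after the high folds of the cluster were seen. The minus strand lies opposite the precursor, so its peaks are no measure of the precursor's parts, and strand marking was not tested in the cluster. Minus-strand peaks held 4210 and 4219 input counts in replicates 1 and 2, against 1354 and 1894 on the plus strand. In sums, minus-strand peaks opposite 28S rRNA were 2.50-fold and 2.94-fold above input. They held 7512 and 6080 immunoprecipitate and 3940 and 3695 input counts. The 2 plus-strand peaks over 28S rRNA held fewer, 1185 and 739 against 362 and 336. Minus-strand peaks opposite the 5' external spacer were at 32.1-fold and 34.8-fold. Opposite internal spacer 1 the sums were 296-fold (127 to 914, from 5 input counts, with 0 input in 4 of its 6 peaks) and 48.3-fold (from 26 input counts), and opposite internal spacer 2 131-fold and 83.1-fold. The order among these 3 spacers was not the same on both strands, with the 5' external spacer highest on the plus strand and lowest on the minus strand by sums (in replicate 2, its minus-strand interval of 22.5 to 56.9 overlapped that of internal spacer 1, 32.7 to 74.4).

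Of the 5 top non-coding entries, 4 were labels inside this cluster. In CH507-528H12.1 (ENSG00000280441.3), an intronic peak on chromosome 21 from 8392335 to 8392620, plus strand, was 335-fold above input in replicate 1 and 337-fold in replicate 2 (mean log2 fold 8.39 ± 0.01, SD, n = 2), from 3060 and 2080 immunoprecipitate counts against 12 and 11 input counts. CH507-513H4.1 (chromosome 21, 8209436 to 8209626, intron) had 106 and 46 counts against 0 in both inputs, at least 76.4-fold higher when set against a floor of 3 counts over both inputs. This bound leaves out the error of the immunoprecipitate counts, and the exact 95% lower limit was 61.4. With replicate 1 alone the bound was 46.4 and with replicate 2 alone 27.4. The peak named MIR3648-1 (chromosome 21, 8207735 to 8209110 in replicate 1 and 8208346 to 8209106 in replicate 2) was 230-fold above input in replicate 1 and 101-fold in replicate 2. It spanned 1376 and 761 bases of the 5' external spacer, against 180 bases of the annotated microRNA gene. The peak named MIR3648-2 (8986901 to 8987601 in replicate 1) was 247-fold above input (95% interval 84.1 to 1203) over both libraries and spanned 701 and 726 bases, again against 180. It lay outside the annotated copies of the precursor. These values belong to the whole peaks and are no measure of the microRNAs. CH507-528H12.1 and CH507-513H4.1 were also the labels with the most peaks, 76 and 34 over both lists with antisense peaks counted. Sense peaks in replicates 1 and 2 numbered 17 and 18 in CH507-528H12.1 and 7 and 8 in CH507-513H4.1. Copies of this unit are nearly identical, so the copy each read came from is uncertain. The intervals here and below cover counting error only. They compare the libraries as sequenced.

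**Figure D1:**
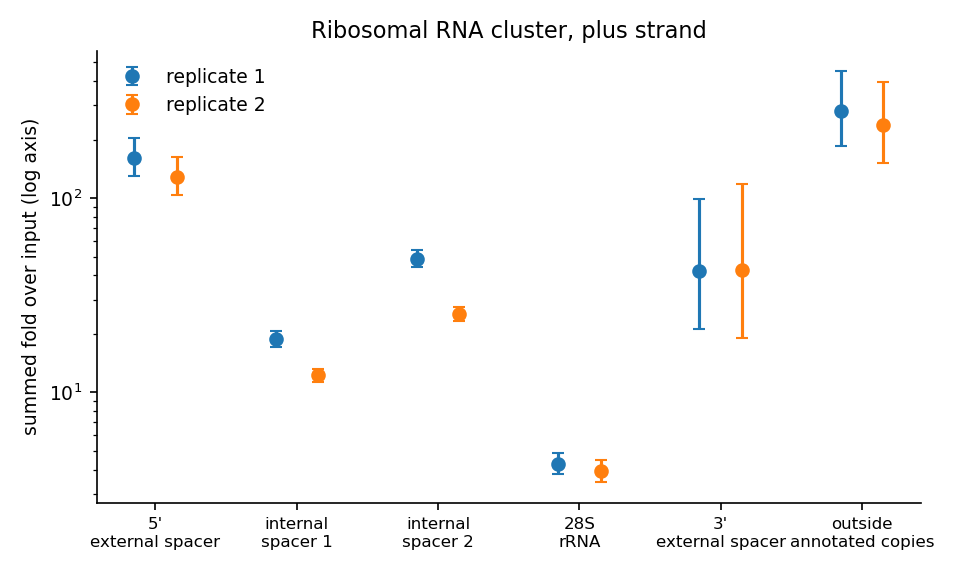
Fold over input of all plus-strand peaks of the rRNA cluster, summed over peaks, for replicates 1 and 2 (log axis, with bars as exact 95% intervals of the count ratio). Peaks are grouped by part of the precursor, with a separate group outside its annotated copies. That group stands at 281 and 238, the 5' external spacer at 161 and 129, and the 28S rRNA at 4.30 and 3.93.

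Small nucleolar and Cajal body RNAs were a further group. A peak in both libraries covered 72 annotated small RNAs. Among them were 47 of 182 with a SNORA name (25.8%), the H/ACA class that guides pseudouridylation, and 12 of 357 with a SNORD name (3.36%), the C/D class that mostly guides 2'-O-methylation. The 72 also held 8 of 29 SCARNA genes (27.6%), 4 of 21 U1 genes and variants and TERC, the RNA of telomerase. SNORD3A (U3, required for cleavage of the rRNA precursor) was 10.4-fold above input (95% interval 9.66 to 11.3 over both libraries), from 2718 and 2292 counts against 388 and 335. SNORD3B-2, a further U3 copy, was 67.8-fold (26.0 to 252) above input and SNORD3B-1 23.4-fold (10.3 to 65.3), SNORD13 stood at 16.8-fold and 6.92-fold in replicates 1 and 2, and SCARNA2 at 2.49-fold (1.86 to 3.34). TERC, singled out after its values were seen, was 2.29-fold (1.95 to 2.69) above input. Values for single U1 and U3 copies are uncertain because near-identical copies share reads.

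Many peaks that the authors named for a protein-coding or long non-coding gene covered a small RNA inside that gene. This was so for at most 53 of the 95 small-RNA peaks in replicate 1 and 44 of 79 in replicate 2. These numbers go by the gene type of the label, and labels counted as hosts include SCARNA2 and TERC, which are small RNAs themselves. The peak named RPL32 lay over SNORA7A and was 31.7-fold (95% interval 19.5 to 55.0) above input, with a mean log2 fold of 5.01 ± 0.12 (SD, n = 2). The RPS2 peak over SNORA64 was 20.5-fold (12.1 to 37.3) above input, the RPL27A peak over SNORA3A 12.9-fold (7.51 to 23.7), the RPL3 peak over SNORD83B 15.1-fold (4.69 to 77.2) and the EIF4A1 peak over SNORA67 12.8-fold (6.15 to 30.9; 19.2-fold and 8.57-fold in replicates 1 and 2). RACK1 (over SNORD95) and RANBP1 (over SNORA77B) belonged here too. RACK1 was 36.2-fold (5.90 to 1488) above input from 1 input count, 23.2-fold in replicate 2 and at least 4.81-fold in replicate 1. RANBP1 had 0 counts in both inputs and was at least 14.1-fold higher against the floor (exact lower limit 10.7), and 7.87-fold and 5.95-fold by the same floor with replicate 1 or 2 alone. Among non-coding hosts, SNHG15 (over SNORA9) stood at 30.1-fold (11.3 to 113) and SNHG8 (over SNORA24) at 10.6-fold (4.46 to 30.4). Whether these reads came from the host transcript or from the small RNA cannot be read from the lists.

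Protein-coding genes with overlapping peaks in both libraries numbered 153. Of the 20 with the highest rank of the authors' fold in both lists, 13 had an intronic peak, 6 had an exonic peak over a small nucleolar RNA, and 1, FASTK (31.7-fold, 95% interval 5.09 to 1309; at least 4.81-fold in replicate 1, 17.8-fold in replicate 2), had another exonic peak. Both inputs held 0 counts at 5 of the intronic peaks. Against the floor of 3 counts, these were higher by at least 20.6-fold in ADK (adenosine kinase; chromosome 10, 74535617 to 74535897), 16.6-fold in ZNF638 (chromosome 2, 71387532 to 71387652), 15.1-fold in SLMAP, 14.6-fold in PRSS3 and 13.6-fold in GPHN, the gephyrin gene. Their exact 95% lower limits were 16.0, 12.7, 11.5, 11.1 and 10.3, and with 1 library alone the bounds ranged from 4.81 to 10.7. The other intronic peaks ranged from 20.3-fold (5.11 to 177) in ATR, a kinase of the DNA damage response, to 99.5-fold (17.2 to 3988) in ANKRD30BL, whose peak (chromosome 2, 132255507 to 132255612) lies in an annotated pseudogene of 18S rRNA, so its reads are uncertain. Between these lay TMEM156 (23.4-fold), ESCO1 (21.6-fold), REEP3 (21.9-fold), JMJD1C (40.7-fold), ITGA3 (46.7-fold) and FBXL17 (49.7-fold), each with only 1 to 3 input counts over both libraries. For 6 of these 8 genes, 1 library had an input of 0, and that library alone gave only at least 7.73-fold (ITGA3), 5.95-fold (JMJD1C), 10.1-fold (FBXL17), 7.87-fold (TMEM156), 5.69-fold (ATR) and 21.9-fold (ANKRD30BL). The other library alone gave from 11.6-fold (TMEM156) to 28.6-fold (ANKRD30BL). Each fold given here belongs to 1 peak of the gene, not to all its peaks. Over all listed peaks of both libraries, before scaling, JMJD1C held 163 immunoprecipitate and 39 input counts in 8 peaks. ADK held 384 and 49 in 18 peaks. After the labels in the rRNA cluster, the genes with the most peaks over both lists, antisense peaks included, were COL6A1 (22), ADK (18) and COL6A2 (13). Sense peaks in replicates 1 and 2 numbered 6 and 11 in COL6A1, 11 and 7 in ADK, and 5 and 4 in COL6A2. COL6A1 and COL6A2 encode chains of collagen VI.

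No listed peak fell in MTA1 itself or in any other of the 15 NuRD members of the list. These are RNAs of the complex's own subunits, and a transcript below the lists' thresholds would not appear.

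The peak lists were also compared with 27 gene lists fixed before the data were examined. Members with a sense peak in both libraries exceeded the expected number in 6 lists (exact stratified hypergeometric test, or Fisher's exact test for non-coding lists, two-sided, Benjamini-Hochberg over the 27 lists). The expected number was that for genes of the same length. For non-coding lists it came from all annotated genes, without length matching. Cytosolic ribosomal proteins had 10 of 79 members (0.573 expected, adjusted p = 3.82e-09), cytoskeleton and adhesion 8 of 53 (0.552 expected, adjusted p = 5.61e-07) and translation factors 3 of 38 (0.260 expected, adjusted p = 0.0118). The MAPK pathway had 3 of 41 (0.409 expected, adjusted p = 0.0350). Abundant long non-coding RNAs had 6 of 36 (0.145 expected, adjusted p = 9.59e-08) and small structured RNAs 4 of 26 (0.105 expected, adjusted p = 2.42e-05). The latter list counted the U3 copies SNORD3A and SNORD3B-1 as separate members, although near-identical copies share reads. Expression in PC-3 cells was not analysed here, so an excess can reflect how strongly a list is expressed.

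Every one of the 10 ribosomal protein genes, and all 12 of their matched peaks, lay over a small nucleolar RNA. With all peaks over annotated small RNAs left out, 0 ribosomal protein genes remained and 1 of the 6 lists, cytoskeleton and adhesion, still passed (adjusted p = 9.43e-07; from 2.13e-09 to 0.00252 over its 8 alternatives). The MAPK list kept its 3 members without those peaks, at 8.18 times the expected number against 7.34 with them, and missed the threshold (adjusted p = 0.0515). Long non-coding RNAs were at 18.7 times (adjusted p = 0.0515) and translation factors at 8.91 times (adjusted p = 0.114) the expected number. All 4 matched peaks of the small structured RNAs lay over a small RNA, so that list could not pass in this setting. In the cytoskeleton and adhesion list, ITGA3 (integrin alpha 3) was 46.7-fold (95% interval 7.79 to 1904) above input (23.6-fold in replicate 1, at least 7.73-fold in replicate 2), ACTB (beta-actin) 10.8-fold (5.73 to 22.6), ACTN1 (an actin cross-linker) 5.24-fold (3.10 to 9.24) and PTK2 (focal adhesion kinase) 3.68-fold (2.44 to 5.66). The remaining members were MYH9, PLEC, PXN and ZYX, and the list's 9 matched peaks had a median of 3.69-fold. The MAPK list rested on EGFR (4.67-fold, 2.82 to 8.04; 7.58-fold in replicate 2), JUN (2.98-fold, 2.02 to 4.45) and MYC (2.96-fold, 1.88 to 4.77). Its call was lost with replicate 2 alone (4.02 times the expected number, adjusted p = 0.105) and with exonic peaks only (6.43 times, adjusted p = 0.116). In the better 50% of each list, 2 of its members had a peak in replicate 1 and 2 in replicate 2, but 0 in both (adjusted p from 2.65e-05 to 1 over its 8 alternatives). Among translation factors, EIF4G3 was 8.61-fold (3.82 to 22.8, with 5.69-fold and 24.98-fold in replicates 1 and 2, mean log2 fold 3.58 ± 1.51, SD, n = 2) and EEF1D 2.91-fold (1.99 to 4.31) above input. The call of this list was lost in the better 50% of each peak list, where only EIF4A1 had a peak in both libraries. There it stood at 18.4 times the expected number against 11.5 with all peaks (adjusted p = 0.239, the highest of its 8 alternatives, with 2.65e-05 the lowest). MALAT1, a nuclear RNA among the long non-coding RNAs, was 6.86-fold (5.85 to 8.08) above input from 494 and 357 counts, and an intronic peak of FTX 20.3-fold (5.11 to 177).

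**Figure D2:**
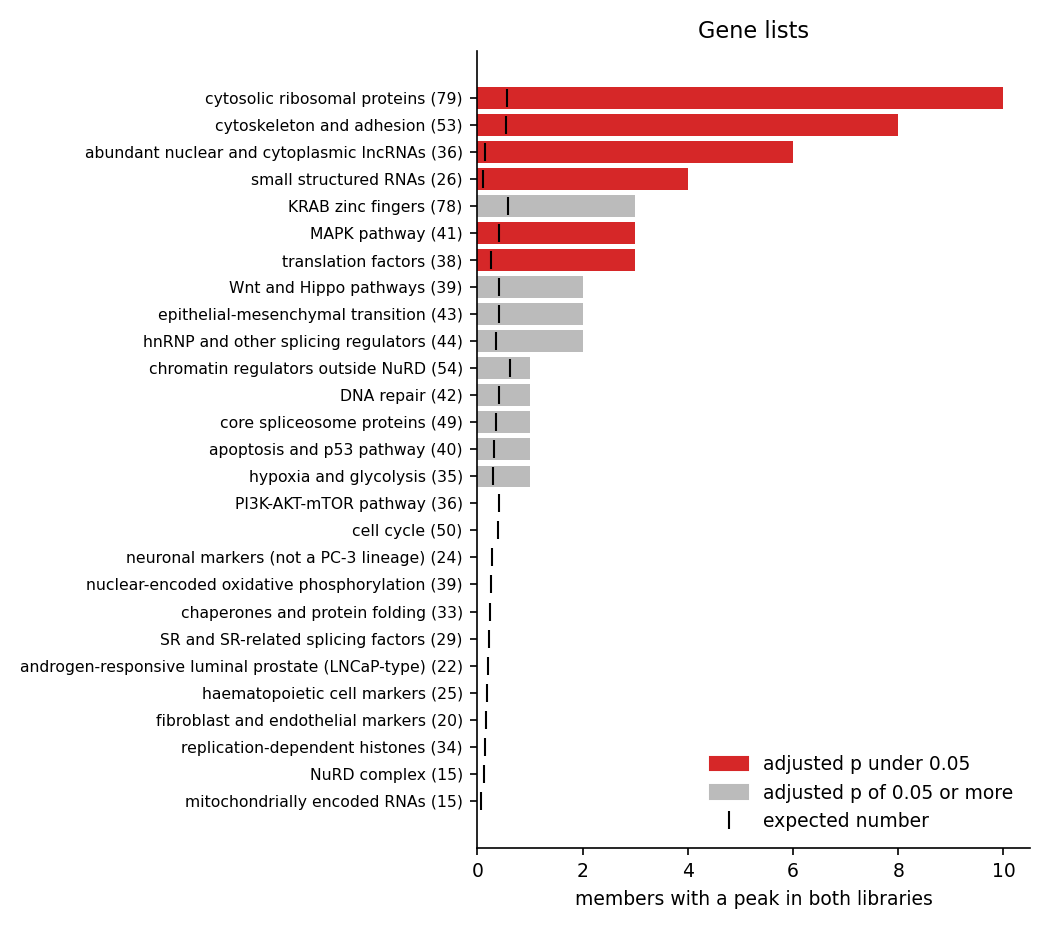
Members of each gene list with a sense peak in both libraries (bars; measured members in parentheses) and the number expected (black ticks). Red bars mark adjusted p under 0.05, with ribosomal proteins at 10 against 0.573 and cytoskeleton and adhesion at 8 against 0.552.

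The other 21 lists did not pass. Splicing regulators of the hnRNP type had 2 members, HNRNPH1 (5.78-fold, 95% interval 2.29 to 17.3) and QKI (mean log2 fold 2.07 ± 0.79, SD, n = 2; 2.84-fold and 6.16-fold in replicates 1 and 2), with adjusted p = 0.162. With 1 library alone this list passed, with 4 members in replicate 1 (adjusted p = 0.0442) and 5 in replicate 2 (adjusted p = 0.00335), of which HNRNPH1 and QKI were in both; over its 8 alternatives the adjusted p ran from 0.00335 to 1. Core spliceosome proteins had SNRNP70 (7.03-fold, 2.86 to 20.8; 4.72-fold and 17.8-fold in replicates 1 and 2; adjusted p = 0.613). The epithelial-mesenchymal list had TJP1 (3.72-fold, 1.99 to 7.29; 5.91-fold in replicate 1) and ITGB1 (3.59-fold, 2.24 to 5.92) with adjusted p = 0.173. It passed with replicate 2 alone (5 members, adjusted p = 0.00447; from that value to 1 over its 8 alternatives). Wnt and Hippo had CCN1 (4.28-fold, 2.68 to 7.05) and CCN2 (2.87-fold, 2.16 to 3.85) with adjusted p = 0.173. KRAB zinc fingers had ZNF248 (8.44-fold), ZNF251 (4.13-fold) and ZNF638, which is a matrin-type zinc finger protein (adjusted p = 0.0771). The better 50% of each peak list held ZNF248 and ZNF638, and there the list passed (adjusted p = 0.0311; from that value to 0.855 over its 8 alternatives). Apoptosis and DNA repair each had only ATR (adjusted p = 0.613 and 0.649), chromatin regulators outside NuRD only NSD2 (5.20-fold, over SCARNA22; adjusted p = 0.842), and hypoxia and glycolysis only HIF1A, whose peaks did not overlap (adjusted p = 0.613). The remaining 12 lists had 0 members with a peak in both libraries (adjusted p = 1 for each). They were NuRD, SR proteins, cell cycle, PI3K-AKT-mTOR, chaperones, nuclear-encoded oxidative phosphorylation, mitochondrially encoded RNAs, replication-dependent histones, androgen-responsive luminal genes, and haematopoietic, fibroblast and endothelial, and neuronal markers. At an unadjusted p under 0.05, 8 of the 27 lists passed.

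Among genes with a peak in either library, ribosomal proteins had a peak in both more often (10 of 14, 71.4%, against 35.4% of other genes), but the difference did not pass (Fisher's exact test, two-sided, adjusted p = 0.245). No other list passed this test either. The number of lists past the threshold was 0, with 2 at an unadjusted p under 0.05.

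By the authors' annotation, peaks lay mostly in exons, 58.8% (95% Clopper-Pearson interval 55.4 to 62.1) in replicate 1 and 62.0% (58.2 to 65.7) in replicate 2. Introns held 21.9% (19.2 to 24.9) and 18.3% (15.5 to 21.5), antisense positions 9.86% and 11.5%, and intergenic positions 9.39% and 8.14%. None of the 4 shares passed a test of the difference between libraries (Fisher's exact test, two-sided, adjusted p from 0.338 to 0.415). Outside the rRNA cluster, exonic peaks had a median of 4.92-fold and 4.66-fold over input in replicates 1 and 2, and intronic peaks 7.66-fold and 8.03-fold, among peaks with at least 1 input count. This difference was not tested, since a peak with few input counts needs a higher fold to be listed. By gene class, 65.6% and 64.9% of peaks were named for protein-coding genes, 15.6% and 17.3% for long non-coding RNAs, and 4.11% and 4.14% for small nucleolar RNAs. Small nuclear RNAs gave 1.06% and 1.48%, and rRNA labels 1.17% and 1.04%, and no class passed the same test (adjusted p = 1 for each).

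**Figure D3:**
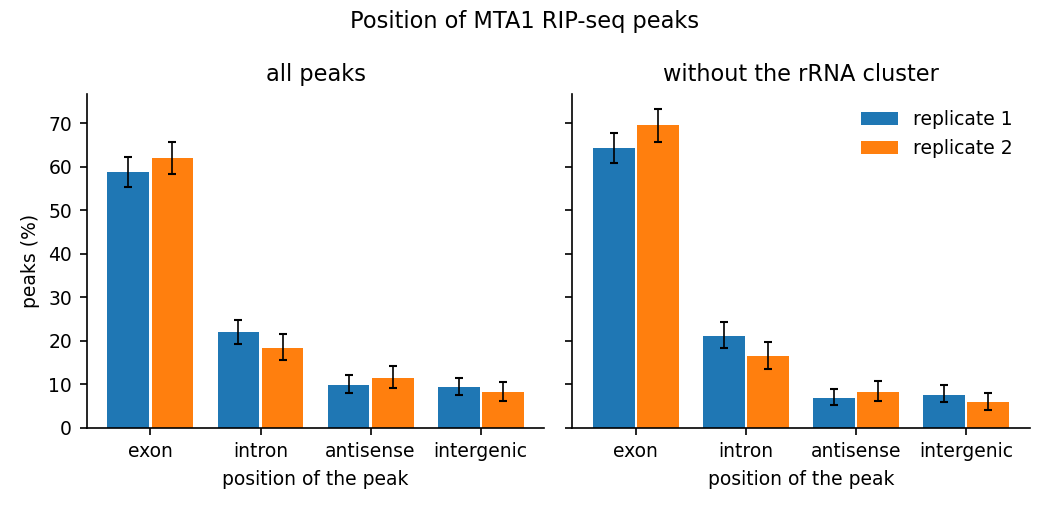
Share of peaks (%) in exons, introns, antisense and intergenic positions in replicates 1 and 2, for all peaks and without the rRNA cluster (bars from 0; error bars are 95% Clopper-Pearson intervals). Exons hold 58.8% and 62.0% of all peaks.

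The lists shared many positions and genes. Of the 676 peaks in the shorter list, 399 (59.0%, 95% Clopper-Pearson interval 55.2 to 62.8) overlapped a peak of the other list by at least 1 base on the same strand. Placing each peak at random within its own gene gave 122 (exact Poisson-binomial test, two-sided, p at or under 1e-300, the smallest written). Of protein-coding genes, 407 had a sense peak in replicate 1, 317 in replicate 2 and 169 in both, against 7.31 expected from lists of these sizes and gene lengths (exact stratified hypergeometric test, two-sided, p = 1.76e-204). Exon and intron class could not be held in the placement, and shared expression can add to both overlaps.

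Matching each peak with its best partner gave 390 pairs, 69 of them in the rRNA cluster. The authors' log2 fold correlated across these pairs with Spearman's rho = 0.81 and Pearson's r = 0.84 (permutation test, 100000 pairings, p = 1e-05 for each, the smallest that number of pairings can give). Without the cluster, rho was 0.73 over 321 pairs. Peaks are not independent replicates, and the lists hold only values past a threshold. In edgeR's quasi-likelihood test on the counts, with Benjamini-Hochberg adjustment, all 390 matched peaks were higher in the immunoprecipitates than in the inputs (2 against 2 libraries). These peaks had been chosen for that excess, so the count is no independent evidence of it. The median fold was 6.03 (quartiles 3.89 and 16.6). It was 57.3 for the 69 peaks in the cluster, 6.97 for 75 peaks over small RNAs elsewhere, 8.40 for 55 other intronic peaks and 4.12 for 142 other exonic peaks. All members of the fixed gene lists among these peaks passed, over all peaks and adjusted over the list alone. For the cytoskeleton and adhesion list this was 9 of 9 peaks by either adjustment.

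**Figure D4:**
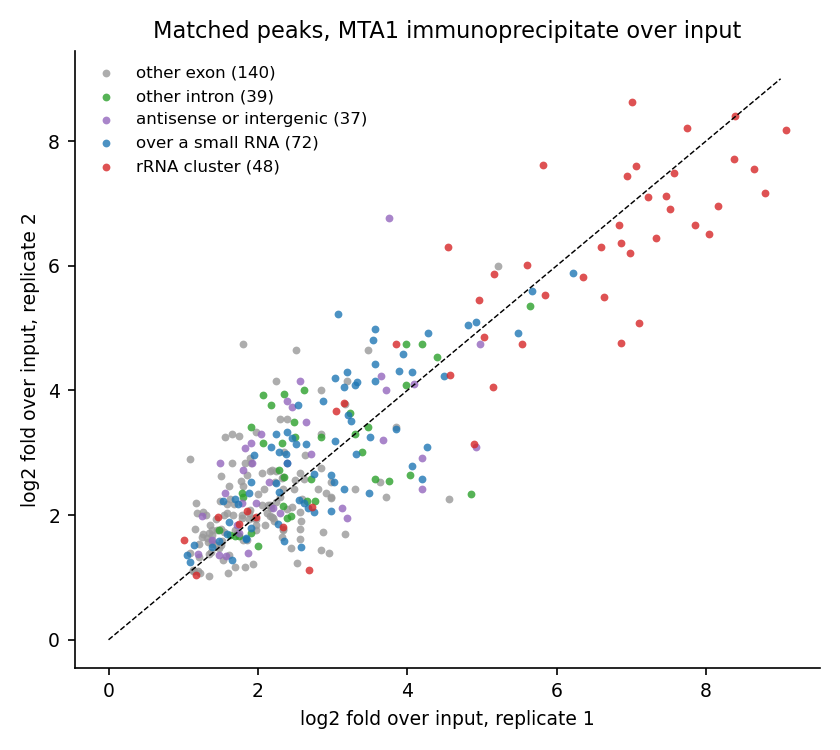
Log2 fold over input in replicate 1 (x axis) and replicate 2 (y axis) for the 336 matched peaks with at least 1 input count in each library, coloured by class (number of peaks in parentheses; dashed line, equal values). The 48 peaks of the rRNA cluster reach the highest values, and the 140 other exonic peaks sit near the lower end.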

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

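The tests of antisense peaks that face a sense peak were chosen only after the result was seen. Intergenic and antisense peaks were not used in the gene comparisons. Each listed peak had been selected for over 2-fold excess, so their sums lie above input by that selection and give only its size, here outside the rRNA cluster. Intergenic peaks summed to 5.86-fold over input (95% interval 5.21 to 6.60) in replicate 1 (59 peaks over 17.7 kilobases, 87.7 against 19.6 counts per kilobase before scaling) and 6.50-fold (5.59 to 7.59) in replicate 2 (35 peaks over 8.93 kilobases, 88.2 against 24.2). Antisense peaks summed to 4.79-fold (4.26 to 5.40) in replicate 1 (53 peaks over 15.9 kilobases, 82.0 against 22.4) and 5.32-fold (4.71 to 6.01) in replicate 2 (49 peaks over 14.6 kilobases, 72.9 against 24.5).

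Antisense signal may come from imperfect strand marking. Of the antisense peaks, 27 of 53 and 25 of 49 faced a listed peak on the opposite strand in replicates 1 and 2, with a median count of 28.9% of that peak's. This share ran from 2.24% to 88.9% in replicate 1 and from 2.44% to 344% in replicate 2. It was over 50% for 4 antisense peaks in each library, and 1 in replicate 2 held more counts than the peak it faced. If 1 rate per library applied, the 5 and 4 sense peaks with at least 300 counts would together cap it at 3.71% and 4.31%. At that rate, at most 6.16 and 4.77 of all 713 and 543 weaker peaks would be expected to have an antisense peak with the lists' minimum of 10 counts, whereas 23 and 18 were listed with at least 90% of their length opposite such a peak (3.74 and 3.77 times as many). This cap rests on SNORD3A: without it, 20.5 and 22.7 would be expected, so imperfect strand marking stays open here too. The share was also unequal between the strong peaks, at 9.72% and 11.8% opposite MALAT1 and at most 2.29% and 2.60% over the others (Fisher's exact test, two-sided, p = 8.04e-13 and 4.61e-12), and the share at MALAT1 would give 47.3 and 39.0 antisense peaks. That test counts reads, which are not independent molecules, and MALAT1 was the strong peak with the highest share. For the 50 antisense peaks that faced no listed peak, strand marking and antisense RNA cannot be told apart, because the sense signal there was not analysed here and the rate may differ between immunoprecipitate and input.

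The excess of H/ACA over C/D small nucleolar RNAs had an odds ratio of 9.69 (95% interval 5.04 to 18.6) for a peak in both libraries. Copies of the same RNA sharing reads did not account for it, since the odds ratio was 8.17 (3.79 to 17.6) with copies counted once. Length may account for it. Among small nucleolar RNAs of 100 to 300 bases, the odds ratio was 1.61 (0.763 to 3.39), with 47 of 180 SNORA and 10 of 57 SNORD covered. Both numbers hold copies of one RNA, such as the U3 copies SNORD3A, SNORD3B-1, SNORD3B-2 and SNORD3D, or SNORA71A to SNORA71D. Copies were not counted once in this length range, so the effect of shared reads on this odds ratio is open. Only 2 of 300 SNORD genes shorter than that range were covered. The interval leaves room for a difference between classes, and no biological explanation was tested.

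For the high folds in the rRNA cluster, depletion of mature rRNA from the input alone would raise the mature parts most, but their median log2 fold differed from that of the spacers by -4.49 (mean of both libraries). This rests on 2 plus-strand peaks over mature rRNA in each library. Whether reads shared between near-identical copies add to the folds stays open. The sum over all plus-strand peaks was 36.6-fold over 17.8 kilobases and 22.5-fold over 15.5 kilobases, against 4.59 and 4.86 summed elsewhere, but these peaks covered only 33.9% and 28.4% of the annotated copies, and counts in the rest were not analysed here. A difference between immunoprecipitate and input in the share of nuclear RNA, or binding to beads or antibody, stays open and untested, as the labels name no mock immunoprecipitate. The design holds no group that bears on a biological explanation, such as contact of MTA1 with the rRNA precursor, and none was tested.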

How the results depend on the processing

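The alternatives without the rRNA cluster, with antisense peaks counted, without small-RNA peaks, and all those on folds over input were chosen after seeing the data. The overlap of peak sets ran from 48.5% to 61.7% and passed its test in each of its 6 alternatives. For the authors' log2 fold, rho was 0.81, and 0.73 without the rRNA cluster. With the authors' p-value it was 0.77. Peak height (0.92) and immunoprecipitate RPKM (0.94) gave higher values, but neither measures excess over input. Genes with a peak in both libraries numbered 218 when named by RefSeq span and 176 with antisense peaks counted; length bins and the rRNA cluster cannot change this number. Gene lists past the threshold numbered 5 to 7, except without small-RNA peaks.

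With the better 50% of each list by the authors' log2 value, genes with a peak in both libraries were 40, which follows from fewer peaks. The exon share was 43.2% and the small nucleolar RNA share 5.72%, and 0 members of the MAPK list had a peak in both libraries. The cause was not tested for these shares and this list. With 1 peak per gene the exon share was 66.1%, and without the rRNA cluster it was 66.9%, with small nucleolar RNAs at 4.62%, by construction. With peaks over annotated small RNAs left out, 1 gene list passed instead of 6, although MAPK (8.18 times), translation factors (8.91 times) and long non-coding RNAs (18.7 times) stayed above the expected number. Ribosomal proteins and small structured RNAs each fell to 0 times the expected number. For small structured RNAs this follows by construction, as all 4 of their matched peaks lay over a small RNA. Over 8 alternatives for the 6 lists past the threshold, 39 of 48 values kept the call, 6 lost it and 3 fell below the expected number. The last group includes, by construction, small structured RNAs without small-RNA peaks. Leaving out a replicate gave 7 lists each time, not the same ones: without replicate 1, hnRNP-type splicing regulators and the epithelial-mesenchymal list joined and MAPK was lost, and without replicate 2 only the splicing regulators joined. It left exon shares from 58.8% to 62.0% and small nucleolar RNA shares from 4.11% to 4.14%, which are the shares of each library and test nothing.

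Of 390 matched peaks past the threshold over input, 389 passed with a replicate block. Whether the number pairs the libraries cannot be settled from 2 pairs (differences between replicates correlated across 247 peaks with r = 0.09 and rho = 0.28). DESeq2 gave 387. With at least 10 input counts, 247 of 247 tested peaks passed. TMM over the matched peaks moved the median log2 fold from 2.55 to 0.10 and left 162, 108 higher and 54 lower, because it sets the shared excess to about 0. The median fold was 5.38 with the totals implied by the authors' p-values, 5.28 without the rRNA cluster, and 5.69 to 6.48 without 1 replicate. Of the 52 named peaks, 23 moved by over 1.5 times without 1 replicate (at most 7.52 times), 15 of them with an input of 0 in a library, where the value is a bound. Bins of exonic length, transcript priority, the 5' end of peaks and all settings for sequence words were not run, since no exon annotation or genome was used; placement without exon and intron classes is the main setting itself. Leaving out a replicate removes the comparison for overlap, shared genes, concordance and the edgeR test, which would have no residual degrees of freedom.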

Other observations

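Intronic peaks were unevenly spread over chromosomes, outside the rRNA cluster; this was tested after it was seen. Chromosome 10 held 37 of 163 intronic peaks (22.7%) in replicate 1 and 16 of 98 (16.3%) in replicate 2, with 5.02% of the total length of protein-coding genes (exact binomial test, two-sided, adjusted over 22 chromosomes, p = 2.15e-13 and 0.000668). These peaks lay in 15 and 7 genes, among them ADK, JMJD1C, REEP3 and ZNF248, so they are not independent. ADK alone held 11 and 7 of them. Without it, chromosome 10 held 26 of 152 (17.1%) and 9 of 91 (9.89%), and the excess passed only in replicate 1 (adjusted p = 5.08e-07 and 0.214). Chromosome 21 held 15 of 163 (9.20%) and 6 of 98 (6.12%) with 1.01% of gene length (adjusted p = 1.94e-09 and 0.00563). Without SIM2, its gene with the most such peaks, it held 13 of 161 and 4 of 96 (adjusted p = 3.05e-07 and 0.214). All these counts hold intronic peaks of genes of any type, such as the non-coding FTX, whereas the share of length is that of protein-coding genes only. Copy number was not analysed here.

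The stretches of 5 megabases with the most peaks of any class, again outside the rRNA cluster, were on chromosome 8 from 140000001 to 145000000 (26 and 27 peaks in replicates 1 and 2, with PLEC, PTK2 and EEF1D) and on chromosome 21 from 45000001 to 50000000 (18 and 22 peaks, with COL6A1 and COL6A2). The first held 0.514% of protein-coding genes and 3.37% and 4.53% of peaks, the second 0.0898% of genes and 2.33% and 3.69% of peaks. Stretches were cut at fixed steps, so one at the end of a chromosome, such as the second, can be shorter than its stated range. COL6A1 peaks singled out after their values were seen were short. One on chromosome 21 from 45992164 to 45992224, plus strand, had 98 and 84 counts against 40 and 33 in input, and an antisense peak at nearly the same place had 37 in each immunoprecipitate against 14 and 10.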
